A study of Homo sapiens with 37 samples.

How the data were processed

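Gene expression was measured in MCF-7 cells, a human breast cancer cell line of luminal epithelial type, on 37 Affymetrix HG-U133 Plus 2.0 arrays, a 1-colour oligonucleotide array on which several short probes together make a probe set. Per the labels' protocols, the cells were serum starved before treatment and RNA was extracted with TRIzol and a QIAGEN RNeasy kit. The treatments were heregulin (HRG), U0126, AG1478, and HRG with either inhibitor. HRG is a growth factor that binds some receptors of the ErbB family. U0126 is an inhibitor of the kinase MEK, and AG1478 an inhibitor of the EGFR kinase. In the combinations the inhibitor was given 20 min before HRG. The labels give no dose for HRG or for either inhibitor.

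The deposited values were probe set signals in units of intensity on a linear scale, made by the authors with GCOS, the array maker's software, per the submitters' processing notes, which name no version and no algorithm. The mean of each array's signals without the lowest and highest 2% lay between 500.0 and 500.1, so the authors had scaled each array to one target, and that scaling was kept. The table held 54675 probe sets, 62 of them control probe sets of the array, with no detection calls. Array description files gave the scan day and the fluidics module of each array and were used only as batch labels. Gene names came from the array's platform annotation, in which 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Symbols were brought up to date through the gene identifier with the RefSeq table of assembly GRCh38.p14, which matched 41043 probe sets. The genome build behind the array's own annotation was not given in the sources used here, and no coordinates were used.

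Signals below the 20th percentile of the whole table, an intensity of 27.9, were raised to it, and log2 was taken, so that the lowest possible value was 4.80. Of the probe sets with 1 gene symbol, those within the upper 60% of probe sets by mean log2 value were kept, which left 25909. For each gene the probe set with the highest mean was used, giving 13658 genes. Values at the floor have no order among themselves.

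Each treatment had 1 array at each of 5, 10, 15, 30, 45, 60 and 90 min. The arrays were therefore grouped into an early window of 3 arrays (5, 10 and 15 min) and a late window of 4 arrays (30, 45, 60 and 90 min), which with the 2 untreated controls made 11 groups. A linear model over all 37 arrays was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior and 26 residual degrees of freedom. Of the 8 comparisons, 5 set the late window of a treatment against its own early window, and the others set 1 such difference against another. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The arrays of a window differ in time as well as in noise, and nothing in the labels says that they came from separate cultures. The p-values therefore measure the spread between these arrays alone. The number of arrays limits the precision. The median standard error was 0.21 (log2) for a response and 0.29 for a difference of responses.

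The share of the HRG response left under an inhibitor was the median, over the genes called and changed at least 2-fold by HRG, of the log2 response with the inhibitor divided by that to HRG alone. The named genes were fixed by rule. They were the 12 highest and 12 lowest called log2 differences of a comparison in which every late array lay on the same side of every early array (for a difference of responses, the same sign at all 4 late times), members of the gene lists, and FOS, EGR1, DUSP6, MYC, CCND1, EGFR, ERBB2, ERBB3 and CYP1A1. Of 30 gene lists, the 29 with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 232 tests, with an estimated correlation and limma's fry beside it. The lists covered immediate early transcription factors, ERK feedback regulators, MEK-dependent transcripts, ErbB ligands and receptors, and targets of SRF, CREB, NF-kB, p53, FOXO, the oestrogen receptor, the aryl hydrocarbon receptor, NRF2, TGF-beta and AP-1. Others covered mRNA decay, heat shock, the unfolded protein response, hypoxia, cholesterol synthesis, growth, mitosis, histones, interferon, ribosomal proteins, oxidative phosphorylation, and markers of luminal epithelium, fibroblasts, blood, basal epithelium and endothelium. The groups, comparisons, lists and alternatives named in the next paragraph were chosen before the data were examined. Comparisons of HRG with an inhibitor against that inhibitor alone, of the early windows against the controls or the inhibitor alone, and of the response with 50% of that to HRG alone were added after seeing the data.

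The alternatives were quantile normalization, a pseudocount or a lower floor (the 5th percentile), no filter or the upper 40% of probe sets, the mean of a gene's probe sets, array weights, no variance trend, only the treatments compared, sampling time or scan day as a block, other windows, the late arrays alone, the controls as the baseline, and each array left out in turn. Sampling time was not taken as a pairing of the arrays, since the deviations of arrays of the same time correlated at a mean of 0.0127 over 70 pairs, against -0.0021 over 420 pairs of different times.

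The steps were tested on simulated data with 100 changed genes per size among 13658. At a log2 change of 1, the HRG response recovered 62% of them, the U0126 effect on it 46% and the comparison of AG1478 with U0126 49%. At a log2 change of 2 these were 83%, 72% and 73%. Unchanged genes wrongly called numbered 2, 6 and 7.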

Results

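Transcript levels were measured over the first 90 min of treatment in MCF-7 cells on 37 arrays. Of these, 2 came from untreated controls and 7 from each of HRG, U0126, AG1478, HRG with U0126 and HRG with AG1478. The titles name 1 control as that for U0126 and the other as that for AG1478, and both were pooled here. The median signal per array ranged from 121 to 156, and 17.6% to 22.3% of an array's probe sets lay at or below the floor. The mean correlation of an array with the others was 0.932 to 0.949. The arrays were scanned on 3 days that partly followed the treatments. All arrays of U0126 and of HRG with U0126 were scanned on day 1, together with the 5 and 10 min arrays of HRG with AG1478. The other 5 arrays of HRG with AG1478 and all of AG1478 alone were scanned on day 2, and HRG alone and the controls on day 3. Levels on different days were therefore compared only as changes within a treatment, unless stated. All values are log2 signals, and each comparison of windows rests on 3 early and 4 late arrays.

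The first comparison asked which transcripts HRG changed between the early and the late window. NR4A3, an orphan nuclear receptor, had the largest rise, from 4.98 ± 0.30 (SD, n = 3) to 11.17 ± 0.96 (SD, n = 4), a log2 difference of 6.20 (SE 0.42, adjusted p = 2.57e-12). Its early values lay near the floor of 4.80, and the mean of the controls was 5.16. The zinc finger factor EGR4 rose by 4.18 (SE 0.61, adjusted p = 4.61e-05), the AP-1 subunit FOSL1 by 3.98 (SE 0.69, adjusted p = 0.000437) and the small MAF protein MAFF by 3.45 (SE 0.38, adjusted p = 2.75e-07). The other highest differences were those of FOSB (3.22), ARC (3.06), NR4A1 (2.81), TMEM88 (2.62), the small GTPase GEM (2.61), ZNF674-AS1 (2.58), EGR3 (2.55) and CCN2, a secreted matricellular protein (2.46). Each had all 4 late arrays above all 3 early ones. Other probe sets gave 5.05 and 0.17 for NR4A3 and 1.62 and 0.55 for NR4A1. With the floor at the 5th percentile the NR4A3 probe set of 0.17 was the one used, and the gene's call was lost in all 3 HRG treatments. Against the controls, ZNF674-AS1 differed by -2.22 in the early window (adjusted p = 0.734) and by 0.36 in the late one (adjusted p = 0.911).

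In all, limma called 132 of 13658 genes in the HRG response, 114 higher and 18 lower, of which 65 rose and 8 fell at least 2-fold. The fallen genes included PPP1R3C, a regulatory subunit for glycogen metabolism (-1.36, SE 0.29), DDIT4, an inhibitor of mTORC1 signalling (-1.08, SE 0.26), MICOS10P1 (-1.25), TCHH (-0.98), SIX4 (-0.91), FTX (-0.84), ARRDC3 (-0.76) and ZNF862 (-0.72). Probe sets of MIR99AHG (-1.99), GPLD1 (-1.82), LINC00537 (-1.24) and MCF2L (-1.20) also fell, but each of these genes had another probe set of opposite sign. For MCF2L that was 1.67, while its other probe sets fell (-1.17, -0.74 and -0.19). Those of GPLD1 gave 0.15, 0.16 and -0.14. The count was 82 without the HRG array of 10 min (5 lower), 82 without that of 90 min (7 lower) and 218 without that of 30 min (46 lower). With array weights 78 of 299 called genes were lower, and with time as a block 77 of 290. Time overlaps the windows, so that block set the fitted level of 90 min against that of 5 min, not window against window.

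Immediate early transcription factors rose together in the HRG response. Of 29 measured, 19 were called higher and none lower, and 27 were higher when adjusted over the list alone (median 1.50, camera adjusted p = 5.38e-74, 3.08e-06 with an estimated correlation). Of 16 ERK feedback regulators, 5 were called higher, among them ERRFI1 (2.38), TRIB1 (2.31) and DUSP5 (2.07), with 10 adjusted over the list alone (estimated-correlation adjusted p = 0.000144). Of 18 MEK-dependent transcripts, 6 were called higher, including FOSL1, MAFF, PHLDA1 (2.29) and the cytokine LIF (1.90), with 10 adjusted over the list alone (adjusted p = 0.00129). SRF and actin cytoskeleton targets had 5 of 12 higher, with CCN2, CCN1 (2.25) and SRF itself (1.50), and 6 adjusted over the list alone (adjusted p = 0.000283). CREB targets had 6 of 13 higher, including SIK1 (1.51) and ATF3 (2.14), and 8 adjusted over the list alone (adjusted p = 3.08e-06). TGF-beta and SMAD targets had 4 of 14 higher, with KLF10 (1.93), JUNB (1.64) and ID1 (1.40), and 5 adjusted over the list alone (list median 0.08, adjusted p = 0.000523). KLF10, JUNB and ID1 are also on the immediate early list. So are NR4A1, NR4A3, FOSB and ATF3 of the CREB list, and FOSL1 and MAFF of the MEK-dependent list. Calls of these lists, here and under the inhibitors, are therefore not separate results. Among 12 aryl hydrocarbon receptor targets, TIPARP alone was called (1.03), with 2 higher adjusted over the list alone (adjusted p = 0.0169). These p-values are from camera with an estimated correlation, adjusted over all lists and comparisons, and so are those that follow where the estimate is named.

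The remaining lists called in the HRG response were lost with an estimated correlation. They were mRNA decay and translation control (ZFP36, which binds AU-rich elements, 2.01; DDIT4 lower; adjusted p = 0.210 with an estimated correlation), p53 targets (GDF15 0.99, GADD45A 0.995 and CDKN1A 0.60 higher of 17; adjusted p = 0.202) and heat shock (DNAJB1 0.82 higher of 10; adjusted p = 0.187). No list call was made for ErbB ligands and receptors, FOXO, oestrogen receptor, NF-kB, NRF2, hypoxia, AP-1 and invasion, cholesterol synthesis, growth, mitotic, histone, interferon, ribosomal or oxidative phosphorylation lists. Luminal markers as a list did not differ (median -0.01, adjusted p = 0.890), with CLDN4 higher (0.86). Markers of fibroblasts (adjusted p = 0.826), blood (0.505) and basal epithelium (0.704) were not called, and endothelial markers had 2 measured genes, too few for the test.

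FOS and EGR1 had early means above the controls by 1.90 and 1.64, differences that did not pass the test (adjusted p = 0.668 and 0.441). FOS was 11.97 ± 0.86 (SD, n = 3) early and 13.01 ± 1.0 (SD, n = 4) late, and EGR1 14.76 ± 0.53 and 15.44 ± 0.31, against control means of 10.07 and 13.12. Neither passed the test between windows (FOS 1.04, adjusted p = 0.596; EGR1 0.68, adjusted p = 0.660). DUSP6 (1.27, adjusted p = 0.195), MYC (0.63, adjusted p = 0.190), CCND1 (0.08), EGFR (-0.01), ERBB2 (-0.16), ERBB3 (-0.14) and CYP1A1 (0.07) did not pass either. Against the 2 controls, scanned on the same day, the late HRG arrays were higher for FOS (2.94, adjusted p = 0.00236), EGR1 (2.32, adjusted p = 0.000537), MYC (1.07, adjusted p = 0.00578) and IER2 (2.18, adjusted p = 2.05e-07). That comparison called 186 genes, 136 higher and 50 lower, 90 of them among the 132 called between windows. The early HRG arrays against the controls called 0. At an unadjusted p under 0.05 there were 688, about as many as chance alone would give.

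**Figure D1:**
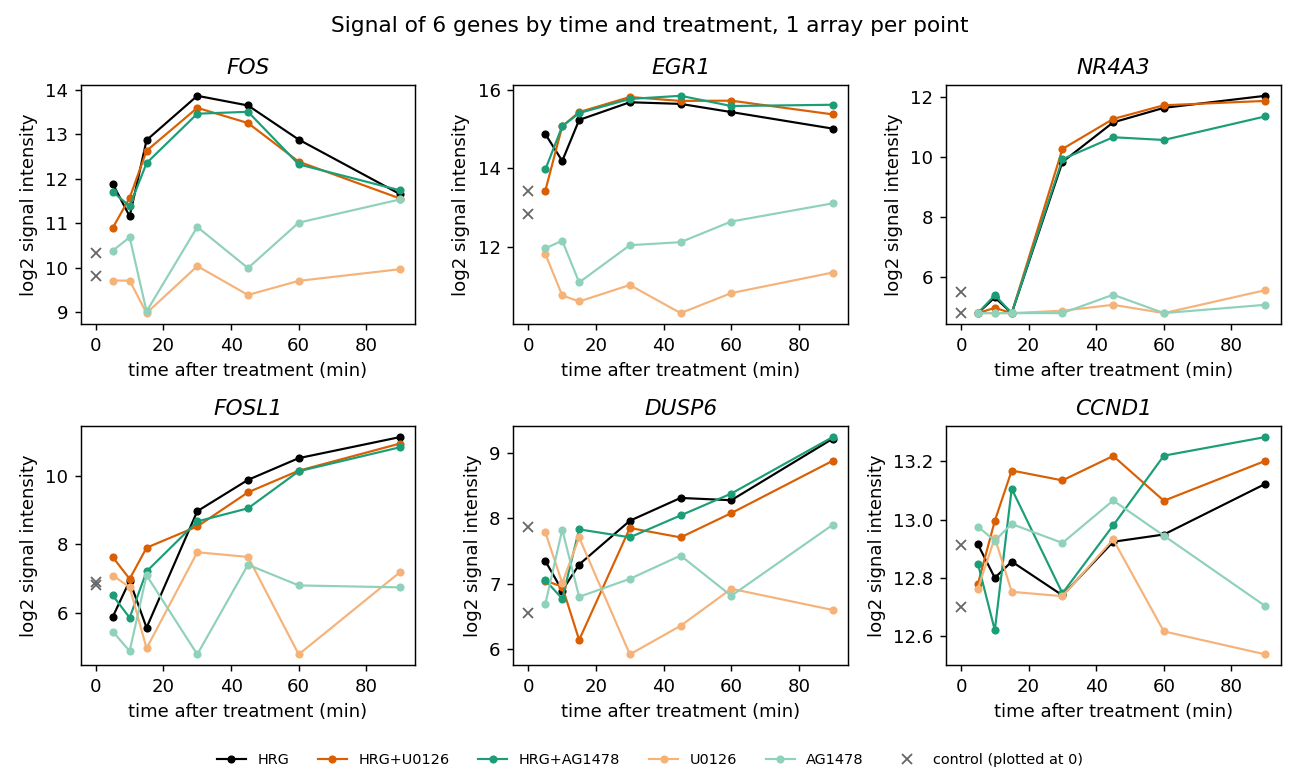
Log2 signal intensity of FOS, EGR1, NR4A3, FOSL1, DUSP6 and CCND1 against time in minutes, with 1 array per point, lines joining the arrays of a treatment, and crosses for the 2 untreated controls. NR4A3 lay near the floor through 15 min in every treatment and was above 9 from 30 min in the 3 treatments with HRG.

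U0126 and AG1478 alone were compared between windows to ask what each inhibitor changed without HRG. After U0126 alone the MEK-dependent transcripts DUSP6 and EPHA2 had log2 differences of -1.06 and -1.04, neither past the test. The list had a median of -0.22 over 18 genes and was called by camera (adjusted p = 0.00931), but not with an estimated correlation (adjusted p = 0.519). Mitotic genes (median 0.09; adjusted p = 0.305 with an estimated correlation) and histone genes (median -0.19; adjusted p = 0.202) were likewise called at the preset correlation alone. After AG1478 alone, EGR1 differed by 0.74 (adjusted p = 0.657) and FOS by 0.83 (adjusted p = 0.724), and the histone (median -0.13; adjusted p = 0.359 with an estimated correlation) and ribosomal protein lists (median 0.12; adjusted p = 0.709) were called at the preset correlation alone. No gene was called by limma for either inhibitor. At an unadjusted p under 0.05 there were 634 genes for U0126, fewer than chance alone would give, and 1034 for AG1478, more than that. Leaving out the AG1478 array of 30 min gave 4 calls, and leaving out that of 5 min gave 1.

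HRG with U0126 was compared between windows to ask what HRG changed with the MEK inhibitor present. NR4A3 rose by 6.43 (SE 0.42, adjusted p = 8.56e-13), from 4.86 ± 0.10 (SD, n = 3) to 11.29 ± 0.72 (SD, n = 4), MAFF by 3.17 (SE 0.38), EGR4 by 3.10 (SE 0.61) and NR4A1 by 2.93 (SE 0.49). FOSB (2.91), EGR3 (2.63), GEM (2.32), ZNF235 (2.30), CCN2 (2.23), CCN1 (2.21) and CSRNP1 (2.18) were also among the highest. GBP1, an interferon-inducible GTPase, rose by 3.06 (SE 0.46) with the probe set used, while its other probe set differed by 0.80. The lowest were MGC15885 (-2.03), DAO (-1.96), TCHH (-1.01), CCDC13 (-1.01), PLA2G6 (-0.90), DTWD1 (-0.75), CCDC51 (-0.68), ABHD16A (-0.55), RNF167 (-0.55) and NSMCE1 (-0.34), of which CCDC13, PLA2G6 and DTWD1 had other probe sets of opposite sign.

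Of the lists under U0126, immediate early factors had 20 of 29 genes called higher and 27 adjusted over the list alone (estimated-correlation adjusted p = 3.08e-06). MEK-dependent transcripts had 5 of 18 higher, MAFF, PHLDA1 (1.98), LIF (1.79), IER3 (1.66) and DUSP4 (1.25), with 10 adjusted over the list alone (adjusted p = 0.00271). ERK feedback regulators had 5 of 16 (9 adjusted over the list alone, adjusted p = 0.00109), SRF targets 5 of 12 (6 adjusted over the list alone, adjusted p = 0.00134), CREB targets 7 of 13 (8 adjusted over the list alone, adjusted p = 3.08e-06) and TGF-beta targets 4 of 14 (6 adjusted over the list alone, adjusted p = 0.000200). TIPARP rose (1.29), and its list of aryl hydrocarbon receptor targets was called (adjusted p = 0.00621). The unfolded protein list was called with PPP1R15A (0.82) and CEBPB (0.42) higher (adjusted p = 0.010), as were mRNA decay with ZFP36 (1.59, adjusted p = 0.0485) and p53 targets with GADD45A (1.01) and GDF15 (0.69, adjusted p = 0.0467). Heat shock (adjusted p = 0.0588 with an estimated correlation), cholesterol synthesis (0.359) and growth (0.509) were called at the preset correlation alone.

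Limma called 109 genes under U0126, 99 higher and 10 lower. No gene was called lower without the array of 5 min (56 calls) or with only the treatments compared (34 calls). The count was 70 without the array of 90 min, 277 without that of 30 min and 187 without those of 15 and 30 min, which stood apart from the other 35 arrays (244 genes below all of them by more than 0.3). Against U0126 alone at the late times, on the same scan day, HRG with U0126 called 245 genes. FOS was 2.92 higher (adjusted p = 7.82e-05), EGR1 4.78 (adjusted p = 2.23e-12) and DUSP6 1.69 (adjusted p = 0.00817). In the early window EGR1 (3.58, adjusted p = 6.76e-07) and CCN1 (1.91, adjusted p = 0.0361) were the 2 genes called.

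HRG with AG1478 was compared in the same way. NR4A3 rose by 5.63 (SE 0.42, adjusted p = 4.32e-11), from 5.00 ± 0.34 (SD, n = 3) to 10.63 ± 0.58 (SD, n = 4), EGR4 by 4.20 (SE 0.61), MAFF by 3.17 (SE 0.38), FOSL1 by 3.14 (SE 0.69) and HBEGF, a ligand of the EGF receptor, by 3.07 (SE 0.76). ARC (3.02), the MAP kinase phosphatase DUSP2 (2.91), NR4A1 (2.58), EGR3 (2.52), GEM (2.45), RASD1 (2.16) and ERRFI1, a feedback inhibitor of EGFR (2.13), followed. The lowest were VPS37D (-1.74), IRX4 (-1.64), PEMT (-0.72), the mitochondrial isoleucyl-tRNA synthetase IARS2 (-0.70, SE 0.11), NCBP1 (-0.69), CALHM2 (-0.64), RMND1 (-0.60), TMEM59 (-0.59), AKAP9 (-0.53), GUSB (-0.46), CTSH (-0.45) and BEX3 (-0.43).

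Under AG1478, immediate early factors had 18 of 29 higher (25 adjusted over the list alone, estimated-correlation adjusted p = 2.18e-05), ERK feedback regulators 4 of 16 (8 adjusted over the list alone, adjusted p = 0.00240) and MEK-dependent transcripts 4 of 18 (10 adjusted over the list alone, adjusted p = 0.00916). SRF targets had 4 of 12 (6 adjusted over the list alone, adjusted p = 0.00916), CREB targets 5 of 13 (9 adjusted over the list alone, adjusted p = 0.000107) and TGF-beta targets 3 of 14 (5 adjusted over the list alone, adjusted p = 0.00271). Ribosomal proteins (median -0.09, adjusted p = 0.721 with an estimated correlation) and oxidative phosphorylation (median -0.12, adjusted p = 0.521) were called at the preset correlation alone. In all, 120 genes were called, 98 higher and 22 lower. The early arrays of 5 and 10 min were scanned on another day than the rest, and with scan day as a block 14 genes were called, 1 of them lower. Only the treatments compared gave 81 calls, 1 lower, no variance trend gave 70, 5 lower, and leaving out the array of 5, 10, 60 or 90 min gave 70, 63, 66 and 58. The lower genes numbered 116 of 236 without the array of 45 min. They were 96 of 276 with time as a block, which set the fitted level of 90 min against that of 5 min. Against AG1478 alone at the late times 152 genes were called, with FOS 1.89 higher (adjusted p = 0.0307) and EGR1 3.22 higher (adjusted p = 3.12e-08), and in the early window EGR1 was higher (3.08, adjusted p = 2.54e-05) and MACC1 (-0.85) and GNG10 (-1.15) lower. Of the 3 early combination arrays, 2 were scanned on another day than AG1478 alone, so these early differences are confounded with scan day.

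The shares of the HRG response left under each inhibitor were compared over the 73 genes that HRG changed at least 2-fold. All 73 differed in the same direction with either inhibitor. The median share left was 0.890 under U0126 (quartiles 0.775 and 0.989) and 0.839 under AG1478 (quartiles 0.678 and 0.939), and 52 and 51 of the 73 were themselves called. The 65 genes that rose had median shares of 0.904 and 0.860 and held all of these calls. The 8 that fell had medians of 0.482 under U0126 (0.101 to 0.700) and 0.553 under AG1478 (0.118 to 0.678), with none called under either inhibitor. Genes chosen for a large change on the HRG arrays tend to change less on other arrays, which can lower these shares. With genes chosen on other arrays the median shares were 0.861 under U0126 and 0.868 under AG1478, so a lowering was not seen for U0126. That run was not split by direction. Of the 8, MIR99AHG, GPLD1, LINC00537 and MCF2L also have another probe set of opposite sign. Whether an inhibitor weakened these falls was not settled. With scan day as a block, 7 of the 73 were called under AG1478, at a median share of 0.704 (quartiles 0.526 and 0.878), all in the same direction. The median standard error of these responses was then 0.39, against 0.26 without the block, and under U0126 the same 52 genes were called. The HRG arrays were all scanned on day 3 and those of HRG with U0126 all on day 1. The block could therefore not move their log2 differences, and the unchanged calls under U0126 are no check on scan day. FOSL1 had 3.98 with HRG alone, 2.27 under U0126 and 3.14 under AG1478. DPP9 had 1.87 with HRG alone, 0.02 under U0126 and 0.19 under AG1478, and TMEM88 had 2.62, 1.15 and 1.29. DPP9 was named after its values were seen. A test of whether the response exceeded 50% of that to HRG alone, chosen after seeing the data, was passed by 34 genes under U0126 and 29 under AG1478, all of them among those that rose, and no gene was shown to lie below that level.

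**Figure D2:**
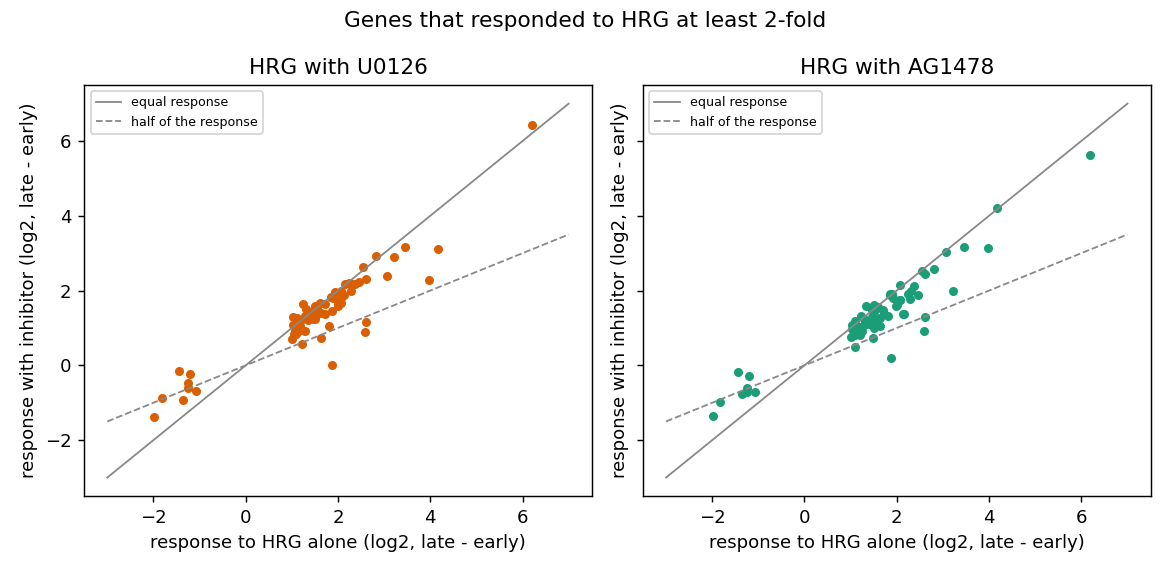
Log2 response (late minus early) of the 73 genes changed at least 2-fold by HRG, with the response to HRG alone on the x axis and that with U0126 or AG1478 on the y axis, 1 point per gene. The solid line marks an equal response and the dashed line 50% of it, and all 73 points have the same sign on both axes.

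The differences between responses were tested directly. For U0126, FOS differed by -0.05 (SE 0.71), EGR1 by 0.34 (SE 0.50), DUSP6 by 0.15 (SE 0.58), MYC by -0.17 (SE 0.28) and CCND1 by 0.10 (SE 0.17), and limma called 0 genes, with 568 at an unadjusted p under 0.05. For AG1478, FOS differed by -0.10 (SE 0.71), EGR1 by 0.21 (SE 0.50) and DUSP6 by -0.14 (SE 0.58), and 0 genes were called, with 402 at an unadjusted p under 0.05. Both unadjusted counts lay below what chance alone would give. Immediate early factors (median -0.21, camera adjusted p = 0.0300), mitotic genes (median 0.15, 0.0300) and ribosomal proteins (median -0.11, 0.00417) were called as lists for AG1478 at the preset correlation, with adjusted p = 0.684, 0.404 and 0.631 with an estimated correlation. The count for U0126 was 1 without the HRG with U0126 array of 30 min. With scan day as a block the count for AG1478 was 4. On the late arrays alone, which differ in scan day between treatments, 1111 genes differed between HRG with U0126 and HRG, and 576 between HRG with AG1478 and HRG.

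AG1478 was set against U0126 by the same test. CCDC13, a coiled-coil protein, was the 1 gene called (1.82, SE 0.30, adjusted p = 0.010). At an unadjusted p under 0.05 there were 681 genes, about as many as chance alone would give. CCDC13 was 9.85 ± 0.13 early and 8.84 ± 0.38 late with HRG and U0126, and 8.80 ± 0.12 early and 9.62 ± 0.24 late with HRG and AG1478 (SD, n = 3 and 4). Its other probe sets differed by 0.88 and -1.04 between windows under U0126. The cholesterol synthesis list was called at the preset correlation (median -0.17, adjusted p = 0.404 with an estimated correlation). No gene was called without the 5 min array of either treatment, without the HRG with U0126 arrays of 15 and 30 min, with the mean of a gene's probe sets, with only the treatments compared or with the other windows. With scan day as a block 4 genes were called, and CCDC13 (1.76) was not among them.

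The called genes of the 3 HRG treatments, which share no arrays but share 1 variance estimate per gene, overlapped. The chance numbers of shared genes take the calls as independent and so may be too low. Of the higher genes, 80 were shared by HRG alone and HRG with U0126 (0.826 by chance), 78 by HRG alone and HRG with AG1478 (0.818) and 68 by both combinations (0.71). TCHH was the 1 lower gene shared by HRG alone and HRG with U0126, and the other pairs shared 0. In all 3 comparisons 65 genes were called in the same direction. With scan day as a block, HRG alone and HRG with U0126 shared 77 higher genes, HRG with AG1478 shared 7 and 6 with these, and 6 genes were called in all 3. HRG alone and HRG with U0126 were each scanned within the same day, so the block could not move their log2 differences. The 77 are therefore no check on scan day. Among the 65 genes that rose at least 2-fold with HRG, 46 were highest at 90 min, 18 at 60 min and 1 at 45 min. With U0126, 44 were highest at 90 min and 11 at 60 min, and with AG1478 37 and 21. The time of the highest value was the same as with HRG alone for 43 genes under U0126 (34.3 by chance) and 50 under AG1478 (32.0 by chance).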

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

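The tests chosen only after the results were seen were those on pairs of splits, the loss of 50% of the response, EGR1 and the MEK-dependent list in the inhibitors alone, the early over late ratio, the calls among late differences, other probe sets of the same genes, RNA degradation, and the search for arrays that stood apart.

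Several single arrays lay far from the other arrays of their treatment. The 3′ over 5′ ratios of the array's control probe sets for GAPDH and actin, which rise as RNA degrades, were 1.01 and 1.86 (log2) in HRG at 10 min, against 0.40 to 0.61 and 0.84 to 1.09 in the other HRG arrays. The actin ratio was 1.02 in HRG with U0126 at 90 min, against 1.38 to 1.51. ERBB2 was 11.004 in U0126 at 15 min, against 10.60 to 10.67, and CCND1 was 12.70 in AG1478 at 90 min, against 12.92 to 13.07. EGR1 was 13.43 at 5 min in HRG with U0126 and 13.97 at 5 min in HRG with AG1478, below the later arrays of each (15.07 to 15.81 and 15.07 to 15.84). About 1 in 20 such tests passes by chance, and here 7 of 70 did.

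CCDC13 differed between the HRG responses under AG1478 and under U0126 by 1.82 (SE 0.30) in the limma test. With scan day as a block it differed by 1.76 (SE 0.38, adjusted p = 0.123), so the call ended mainly through the wider error. Its other probe sets did not move together. Among 6859 probe sets without a single gene name, which no comparison used, 43 were called between the windows of HRG, 27 higher and 16 lower.

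Other ways of dividing a treatment's 7 arrays into groups of 3 and 4 were counted to see whether chance can be excluded. For HRG alone, 2 of 35 splits called at least the real 132 genes, the highest other being 204 with 45, 60 and 90 min set apart, so these splits alone did not exclude chance at a share of 0.05. For HRG with AG1478 it was 2 of 35 (120, highest other 207, with 30, 60 and 90 min set apart), and for HRG with U0126 7 of 35 (109, highest other 568, from a split that put 5, 15 and 30 min together). The highest other split of HRG alone follows time and that of HRG with U0126 the 2 arrays described below, so these point to structure among the arrays. That of HRG with AG1478 puts 45 min with the early arrays and so does not follow time. The higher genes that separate arrays had in common argued against chance agreement. As many as the 80 shared by HRG alone and HRG with U0126 were found in 1 of 1225 pairs of splits, the real one (highest other 16), and the same held for the 78 of HRG alone and HRG with AG1478 (1 of 1225, highest other 2) and the 68 of both combinations (1 of 1225, highest other 14). This covers the shared higher genes and not the lower ones, of which 1, 0 and 0 were shared, and no block on scan day, with which HRG with AG1478 shared 7 and 6 higher genes. The 3 arrays set apart were always taken as early. A split that sets late arrays apart, such as 45, 60 and 90 min, turns risen genes into lower ones, which were not counted. The highest other pair of HRG alone and HRG with AG1478 was of this kind. The low counts of other splits are therefore partly set by the counting. When treatments were swapped within times, 10 of 64 swaps were as large as the 1 call of AG1478 against U0126 (highest other 31). Any split calls at least 0 genes, so the 35 of 35 splits of U0126 and AG1478 alone (highest other 3 and 2) and the 64 of 64 swaps of the U0126 and AG1478 effects say nothing of chance. The highest swaps of these effects, 2777 and 1464, exchanged all 4 late arrays, which points to a constant difference between the treatments, whether from scan day or inhibitor.

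The rise of transcripts after HRG was largely kept under U0126, with a median share of 0.904 over the 65 genes that rose (0.890 over all 73), while the 8 that fell had a median of 0.482. The genes were chosen on the HRG arrays, which can lower shares on other arrays, so the median of the 8 was not traced to the inhibitor. Noise that hides a loss of 50% of the response stays open for most single genes, since 46.6% of the 73 genes were shown to exceed that level. An inhibitor that did not act in these cells may be another explanation. EGR1 was lower in U0126 than in AG1478 alone at 7 of 7 matched times, with differences of -0.14 at 5 min and -1.76 at 90 min. The 18 MEK-dependent transcripts had a median difference of only -0.20 there. EGR1 is 1 gene, AG1478 alone is no untreated baseline, and those arrays were scanned on different days. Action of the inhibitor and scan day therefore cannot be told apart in that comparison. Within scan days, the late EGR1 excess of HRG with U0126 over U0126 alone was larger than that of HRG over the controls. The difference between these excesses, tested over all genes, called 0 genes, so it does not settle whether the inhibitor acted. Between windows, the MEK-dependent list rose by a median of 0.833 with HRG and U0126 and 0.743 with HRG alone. DUSP6 differed by 1.42 and 1.27, neither called. These changes within a treatment leave open an inhibitor that did not act. A response that does not need MEK was not tested, and no phosphorylation was measured.

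On the late arrays alone, 1111 genes differed between HRG with U0126 and HRG. A constant difference between scan days or series is consistent with this, since the early arrays differed by a median of 0.887 of the late difference for the same genes (0.670 for the 576 genes of AG1478). An inhibitor effect that grows with time stays open, since the 0 of these genes called in the difference of responses decide nothing at a median late difference of 0.46, where even at 1 that test recovered 46% of simulated genes. An inhibitor effect already complete at 5 min has the same form as a scan day difference, and the design does not separate them.

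The HRG with U0126 arrays of 15 and 30 min shared 244 genes below all 35 other arrays by more than 0.3, MALAT1 with 7 probe sets and EGFR (7.78 and 8.40 against 9.36 to 9.87) among them. The next highest pair of arrays of the same treatment shared 19 in either direction, and pairs across treatments were not counted. A change of the whole genes was not settled. The 589 other probe sets of the same genes had a median difference of -0.076 (quartiles -0.73 and 0.19), against -1.58 for those chosen. A fall of all probe sets of these genes was therefore not seen. But those chosen were picked for being low in these arrays, and the others have lower mean signals, so a smaller fall was built in. MALAT1 fell in 7 probe sets. Degraded RNA beyond that of other arrays was argued against, as 0 of 4 ratios for GAPDH and actin lay above the range of the other treated arrays. That range includes HRG at 10 min, itself far from its treatment, but U0126 alone at 5 min also had higher ratios (0.96 and 1.60). Within their own treatment, the 30 min array had the highest of both ratios (0.88 and 1.51). That of 15 min had the lowest for GAPDH (0.69) and the next highest for actin (1.40). Some part of degradation was not excluded. Lower recovery of nuclear RNA may have contributed but was not settled, as 6 probe sets of MEG3 and KCNQ1OT1 had a median difference of -0.78, with single values from -3.48 to 0.15. No group of the design separates these arrays from the rest of their treatment, so no biological explanation was tested.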

How the results depend on the processing

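The baselines of inhibitor alone, the runs without the HRG with U0126 arrays of 15 and 30 min, the fluidics module block, scan day as a block for the shares and overlaps, the shares by direction and the reversed columns of fry were chosen after seeing the data. The replicate number of an array is its sampling time, so the time block below is also the block on replicate number.

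The shares of the HRG response left lay within the jackknife SE of their main values under every alternative run (0.252 for U0126, 0.211 for AG1478). That SE was computed from the runs with an array left out, so those runs could hardly lie outside it. It is also wide beside the shares, so staying within it says little of the other alternatives. The furthest from the main values were 1.06 for U0126, without the arrays of 15 and 30 min, and 0.704 for AG1478, with scan day as a block. The shares were 0.861 (U0126) and 0.868 (AG1478) with genes chosen on other arrays, and 0.738 to 0.976 and 0.712 to 0.926 with an array left out. The HRG response called 299 genes with array weights, 290 with time as a block, 213 with windows of 5 and 10 against 45, 60 and 90 min, and 82 to 218 with an array left out. Under U0126 it called 34 with only the treatments compared, 227 with the time block, 169 with the other windows, 187 without the arrays of 15 and 30 min, 245 against U0126 alone, and 56 to 277 with an array left out. Under AG1478 it called 70 without the variance trend, 276 with the time block, 14 with scan day as a block, where the 15 min array is the only early one of its day, and 58 to 236 with an array left out.

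AG1478 alone called 2 genes with the mean of a gene's probe sets, 1 with the module block and 0 to 4 with an array left out. The U0126 effect called 1 with array weights, 2 without the arrays of 15 and 30 min, 1111 on late arrays only and 0 to 1 with an array left out. The AG1478 effect called 4 with the scan day block and 576 on late arrays only. AG1478 against U0126 called 2 without a filter, 4 with the scan day block, CCDC13 not among them, 0 to 2 with an array left out, and 0 with the mean of probe sets, only the treatments compared, the other windows, late arrays only, or without the arrays of 15 and 30 min. Unless a cause is given, the cause was not tested.

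Of 232 list tests, camera called 40 at the preset correlation and 23 with an estimated one, and fry called 26. Fry's count was 24 with the columns of the design reversed and 23 to 26 over 50 random column orders. Its gene SD leaves out each gene's largest rotated effect, which depends on that order, and without standardization all 50 orders gave 21.

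NR4A3 was 0.17 with HRG alone, -0.53 under U0126 and 1.62 under AG1478 with the floor at the 5th percentile, none of them called, where another probe set had the highest mean and was chosen. Among alternatives other than an array left out, results for single named genes were unchanged in direction and call in 1900 cases, lost the call in 204, gained it in 17 and reversed in 1, NR4A3 under U0126. With an array left out, 1035 were unchanged and 162 lost the call. EGR3, EGR4, FOSB, FOSL1, GEM, MAFF, NR4A1 and TMEM88 kept their call in the HRG response throughout, 8 of 24 named genes, as did 4 of 22 under U0126 and 1 of 24 (MAFF) under AG1478. Signals near the floor limit genes such as NR4A3, whose fold depends on it.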

Other observations

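Values in this part were picked after the data were seen, and no cause was tested for them. TXNIP, an arrestin-like protein that limits glucose uptake, had a lower mean at 15, 45 and 90 min than at the other times in all 5 treatments, by -0.59 with HRG, -0.40 with U0126, -0.62 with HRG and U0126, -0.38 with AG1478 and -0.59 with HRG and AG1478. For its relative ARRDC4 the same differences were -0.16, -0.44, -0.32, -0.43 and -0.05.

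In the early window, 119 genes differed between U0126 alone and the controls and 8 between AG1478 alone and the controls. These arrays were scanned on different days from the controls, and treatment and day cannot be told apart for them.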
